A study of Homo sapiens and Mus musculus with 4 samples.

How the data were processed

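Immunoprecipitated RNA was measured on Illumina bead arrays with whole-genome content, human M17 neuroblastoma cells on one design and mouse whole brain on another. There were 4 deposited samples, 1 per group: human DJ-1 precipitate (6 array files), human IgG precipitate (4), mouse WT precipitate with the DJ-1 antibody (3) and mouse KO precipitate with the DJ-1 antibody (1). Groups were taken from the sample titles, and each array file was used as 1 replicate because the series design describes biological replicates. The WT label calls its RNA nonspecific as well, and the title was followed. The labels do not name the gene knocked out in the mouse, which was taken to be that of DJ-1 from the study's subject.

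Per the file headers, the deposited array files were written by BeadStudio 1.5.1.3 with no normalization. Their signal column is a probe intensity on a linear scale, averaged over the beads of a probe, per the file headers. Their detection column, also deposited, is a score that nears 1 for probes above the negative controls. The bead number and bead SD per probe were used to compare arrays. The deposited value tables hold an intensity per probe and sample which equals the mean of the sample's human arrays within 0.0833, so the authors had averaged the arrays without further scaling. The medians of their columns were 84.7 and 90.2 for human DJ-1 and IgG and 141 and 135 for mouse WT and KO. The limits of each array were its number of beads, 30.0 to 42.0 per probe on average on the human arrays and 40.6 to 43.6 on the mouse arrays, and its background. The median intensity over all probes, most of them not detected, was 68.4 to 100.0 in human and 135 to 151 in mouse. The number of arrays limits the precision.

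Human probes were named from the platform's gene table: of 47293 probes 18468 had 1 gene symbol, none had several and 28825 had none in the table. Through Entrez identifiers 18451 of the named probes matched the RefSeq gene table of GRCh38.p14, which changed no symbol. The mouse array files use other probe identifiers than the value table. They were joined by the values themselves, the KO value and the WT mean within 0.07, where the match was unique both ways, which placed 37186 of 46116 rows and 14239 of the 14276 probes detected on an array. In 2972 of 2972 matched probes whose identifier holds a clone accession, the gene table gave the same accession. Of the matched mouse probes 24724 had 1 symbol, 9 several and 12453 none. Coordinates, GC content and transcript length were not used here.

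In R 4.3.3 with limma 3.58.1, the intensities of each species were background-corrected, quantile-normalized and log2-transformed by neqc, with the detection score giving the negative control levels and an offset of 16. Probes were kept where the score exceeded 0.99 on at least 4 human arrays or 1 mouse array, and the probe with the highest mean stood for a gene. Of 304 human genes with 2 or more kept probes, INF2 and SLC30A5 had probes called in opposite directions. Groups were compared with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values are from this fit unless a list is named. Where a probe was detected on no array of a group, a bound replaces the fold: the mean of the other group against the mean of, per array, the higher of the probe's own value and the lowest value among detected probes.

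Gene lists of mitochondrial complex I, complexes II to V, mitochondrially encoded subunits, selenoproteins, glutathione metabolism, antioxidant genes, MAPK and JNK signalling, parkinsonism, ribosomal proteins, translation factors, proteasome, chaperones, ubiquitin and SUMO enzymes, histones, spliceosome, cell cycle, immediate early genes, extracellular matrix, nuclear receptors and cell type markers were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01, with an estimated correlation as an alternative and fry beside it. By fry, which tests for a net shift of a list without regard to the other genes, 18 of 23 human and 0 of 28 mouse lists passed. For change in either direction 23 and 1 passed. A list needed 5 tested members. The counts of lists include 1 that is not described. Mitochondrially encoded subunits had 0 tested in either species, and in human cells the oligodendrocyte, microglia and red blood cell lists had 1 each and the endothelium and choroid plexus lists 4 each, so these were not tested.

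The genes named follow a rule fixed before the data were examined: PARK7, the 12 genes with the greatest difference in each direction among those past the threshold with arrays that do not overlap, and up to 3 members of each list by smallest p. In mouse they are Park7 and, since under 10 genes passed, the 5 smallest p in each direction, and no gene was called in both species. Unnamed loci were counted and not named. TXNRD1, Hbb-bt and Alas2 were named after their values were seen. Detected shares were compared by an exact permutation test, and the species by Spearman and Pearson correlation and a one-sided Fisher exact test against the 500 mouse genes with the highest difference.

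Arrays were compared before they were averaged. The closest pairs, whose log2 signals differed by an SD under 0.15, were DJ-1 arrays 1 to 3, IgG arrays 1 and 3 and WT arrays 2 and 3. Their median squared differences were 1.67 to 3.78 times what the reported bead SD gives. That SD was used undivided by the root of the bead number, so these ratios may be too low. The arrays were kept as separate replicates and averaged in an alternative. An excess over bead error does not tell separate cultures or animals from repeated hybridizations. The files name no slides. Bead numbers per probe placed DJ-1 arrays 1 to 3 and IgG arrays 1 to 3 in a set with fewer beads, and DJ-1 arrays 4 to 6 and IgG array 4 in a set with more. The arrays carry numbers in their column headers. Deviations from the group means correlated at 0.12 to 0.48 for DJ-1 and IgG arrays of the same number, at 0.03 to 0.40 for other numbers within a bead set and at -0.48 to -0.01 across sets, and 1 of 4 DJ-1 arrays correlated best with the IgG array of its number. The numbers were therefore not used to pair arrays, and a fit with them as a block is an alternative.

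The fit was tested on simulated data with the means and spread of the real genes. For human, 30, 40, 50 and 50 of 50 genes changed by 0.5, 1, 2 and 3 on the log2 scale were recovered among 8299, with 10 false calls. For mouse, 0 of 50 were recovered at each of these sizes among 8854 genes, with 0 false calls. A list shifted by 0.8 was found in both species. The simulated genes varied independently of each other. In the real data the estimated correlation within a list reached 0.25 for the human cell cycle and 0.99 for mouse complex I. The simulation therefore does not test the preset correlation of 0.01. Alternatives covered background correction, scaling, filters, probes per gene, priors, array weights, thresholds, each array left out, the bead set and the averaged arrays.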

Results

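RNA that came down with antibody precipitates was measured on whole-genome bead arrays in order to find transcripts associated with DJ-1, the protein encoded by PARK7 and lost in a recessive form of parkinsonism. In human M17 cells, a neuroblastoma line, RNA precipitated with an antibody against DJ-1 was hybridised to 6 arrays and RNA precipitated with a nonspecific IgG to 4 arrays. In mouse whole brain the DJ-1 antibody was used throughout, on 3 arrays from wild-type (WT) brain and on 1 array from knockout (KO) brain. The study's design speaks of biological replicates, and each array was taken as 1 replicate. The labels do not say which arrays came from separate cultures or animals, so the p-values measure the spread between these arrays, which may in part be technical. The share of detected probes was 21.8% ± 0.307 (SD, n = 6) with DJ-1 and 20.9% ± 0.981 (SD, n = 4) with IgG, a difference of 0.883 percentage points that did not pass an exact two-sided permutation test (p = 0.0571; 210 splits, smallest possible p 0.00476). The call depended on the detection threshold and on single arrays. At a score above 0.95 the difference was 0.982 points and passed (exact permutation p = 0.00952). Without DJ-1 array 1 or IgG array 1 or 3 the exact permutation p fell to 0.0476, 0.0476 and 0.0357, and without IgG array 2 the difference was 0.535 points. Within the set of human arrays with fewer beads per probe the mean shares were 21.9% and 21.1%, and within the set with more beads 21.7% and 20.3%. In mouse, 24.8%, 26.4% and 27.0% of probes were detected on the WT arrays and 24.8% on the KO array.

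The human arrays asked which RNAs were recovered with DJ-1 rather than with a nonspecific antibody. PARK7 RNA itself was higher with DJ-1 by 0.43 on the log2 scale (SE 0.0922, adjusted p = 0.00185, n = 6 and 4), a 1.34-fold difference. The transcript with the greatest gain was IGF2, which encodes an insulin-like growth factor: its mean log2 intensity was 12.14 with DJ-1 and 6.14 with IgG, a 64.2-fold difference (log2 6.00, SE 0.420, adjusted p = 5.07e-07). Next came SELENOW, a small selenoprotein (10.7-fold, log2 3.41, SE 0.0974), and GPX4, the peroxidase that reduces lipid hydroperoxides (9.02-fold, log2 3.17, SE 0.104). At the other end, NCL, which encodes nucleolin, was 5.63-fold lower with DJ-1 (log2 -2.49, SE 0.315, adjusted p = 4.33e-05), and the growth factor PTN was 3.85-fold lower (log2 -1.94, SE 0.591, adjusted p = 0.0138).

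The other transcripts with the greatest gains, each with every DJ-1 array above every IgG array, were TRIOBP, an actin-binding protein (log2 2.89), SCARA3, a scavenger receptor (2.86), DENR, a factor of translation re-initiation (2.73), the ubiquitin ligase MGRN1 (2.63, detected on 3 of the 4 IgG arrays), the AP-1 subunit JUND (2.56), ANKRD9 (2.43) and SIVA1 (2.39). ZBED3 and FGFRL1 were detected on all 6 DJ-1 arrays and on none of the 4 IgG arrays, and were therefore at least 6.80-fold and at least 5.19-fold higher with DJ-1. The transcripts with the greatest losses after NCL and PTN were LUM, the proteoglycan lumican (log2 -1.54), the adhesion molecule ALCAM (-1.54, detected on 5 of the 6 DJ-1 arrays), the microfibril protein MFAP4 (-1.52), the GPI transamidase subunit PIGK (2.83-fold lower), ELMOD2 (-1.47), C1GALT1C1, a chaperone of a Golgi glycosyltransferase (-1.46), the lysosomal protease CTSV (-1.45), AIMP1 (-1.39), the procollagen processing enhancer PCOLCE (-1.37) and MRPL24 (-1.37). PTN was detected on 4 of the 6 DJ-1 arrays. It lay at 7.87 to 8.08 on DJ-1 arrays 1 to 4 and at 5.18 and 5.31 on arrays 5 and 6. The IgG arrays lay at 8.83 to 9.16. NCL lay at 9.21 to 9.49 on DJ-1 arrays 1 to 4 and at 7.98 and 8.01 on arrays 5 and 6. IGF2 lay at 11.38 to 11.75 and at 13.64 and 13.15. FGFRL1, MGRN1 and MFAP4 also differed more from IgG on arrays 5 and 6, while SELENOW and LUM did not split this way. The sizes of such differences thus depend on those arrays.

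**Figure D1:**
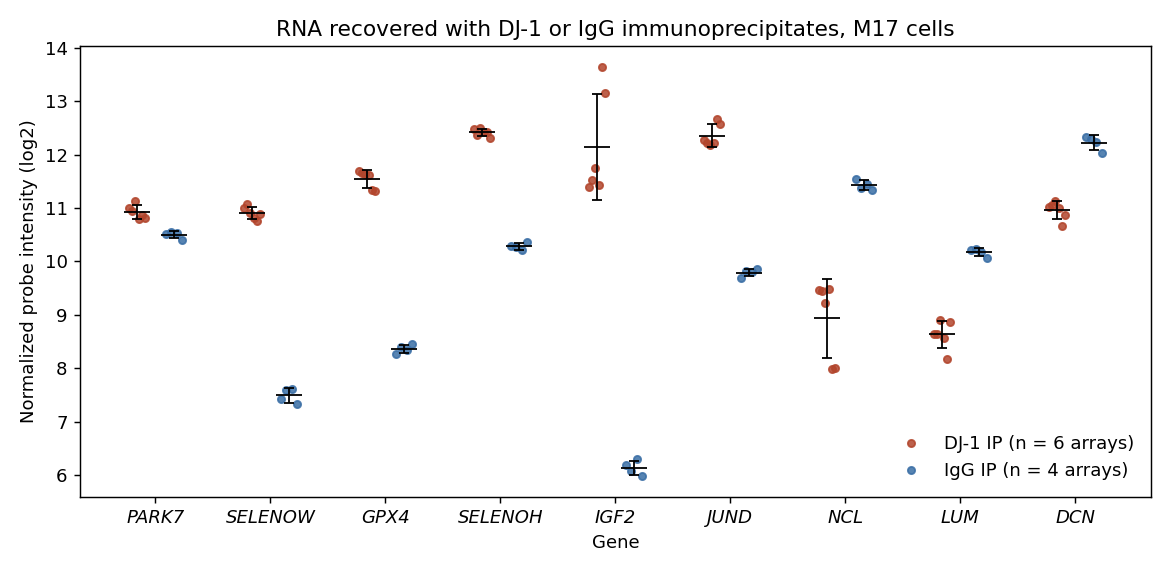
Normalized probe intensity (log2) of 9 genes on each human array, with 6 arrays of DJ-1 immunoprecipitates in red and 4 arrays of IgG immunoprecipitates in blue; black bars give the mean and SD. The arrays of both groups are apart for each gene shown, by 6.00 for the means of IGF2 and by 0.43 for those of PARK7.

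Of the 8299 genes tested, 2202 were higher and 2709 lower with DJ-1 at an adjusted p under 0.05, and 1730 of the higher and 1967 of the lower genes had groups of arrays that did not overlap. The arrays did not overlap in 3736 genes, where chance gives 0.952% of all genes. Changes over 2-fold were more often gains, with 611 genes higher and 154 lower. The split between directions depends on the scaling. With the arrays scaled to a common 75th percentile, 2272 genes were higher and 1117 lower. The median of all genes then moved from -0.10 to 0.06. Every scaling brings the arrays to a common level, so all differences, large or small, are relative to the other genes. They do not give the absolute amount of RNA recovered with each antibody. DJ-1 arrays 5 and 6 stood apart from DJ-1 arrays 1 to 4, with correlations across probes of 0.953 to 0.970 between them and 0.988 to 0.996 among arrays 1 to 4. The human arrays fell into sets with different bead numbers, each holding both antibodies; with the set as a block 5281 genes passed, within the set with fewer beads (3 against 3 arrays) 5431, and within the set with more beads (3 against 1) 839.

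Selenoprotein transcripts stood highest among the 23 gene lists tested. Of 14 measured, 13 were higher with DJ-1 and 1 lower, both over all genes and adjusted over the list alone, with a median log2 difference of 1.15 (limma camera, adjusted p = 6.07e-07; adjusted p = 0.0430 with an estimated correlation). SELENOH was 4.38-fold higher (log2 2.13, SE 0.0805) and the plasma peroxidase GPX3 3.59-fold (log2 1.85, SE 0.214), though it was detected on 3 of the 4 IgG arrays. The exception was TXNRD1, the cytosolic thioredoxin reductase, at -0.51 (SE 0.167, adjusted p = 0.0195). Subunits of respiratory complexes II to V also lay higher, with 18 of 39 higher and 4 lower (median 0.25, adjusted p = 0.00275; adjusted p = 0.0430 with an estimated correlation), among them the ATP synthase subunits ATP5F1E (1.37) and ATP5F1D (0.91) and the complex III subunit UQCRQ (1.38). These were the lists whose call held with an estimated correlation.

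Nuclear-encoded subunits of complex I were higher for 14 of 33 and lower for 4 (median 0.27, adjusted p = 0.0305), with NDUFB1 at 1.40, NDUFB10 at 1.23 and NDUFA1 at 0.74. The call did not hold with an estimated correlation (adjusted p = 0.352), with 75th percentile scaling (0.0803), without IgG array 1 (0.0515), with the close arrays averaged (0.0617) or within the arrays with more beads (0.302), and ranged from 0.00281 to 0.352 over all alternatives. Of 72 cytosolic ribosomal proteins 30 were higher and 6 lower (median 0.21, adjusted p = 0.00275; adjusted p = 0.135 with an estimated correlation), including RPLP1 (2.47-fold higher), RPS12 (log2 1.11) and RPS27 (0.83). The call was lost with 75th percentile scaling (adjusted p = 0.0803) and within the arrays with more beads (0.0944), in a range from 0.000104 to 0.135. For these lists the counts adjusted over the list alone were the same. The lists of selenoproteins, respiratory subunits and glutathione metabolism were set with the study's topic known, and are not independent evidence of a direction.

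Extracellular matrix transcripts were lower with DJ-1 for 19 of 23 genes (20 adjusted over the list alone) and higher for none (median -0.76, adjusted p = 3.24e-05; adjusted p = 0.0653 with an estimated correlation). The median ranged from -0.91 to -0.11 over the alternatives, the latter without a detection filter. Besides LUM they included the proteoglycan DCN (-1.26, SE 0.110) and the microfibril component FBN1 (-0.95, SE 0.0949). Proteasome subunits were lower for 25 of 32 and higher for 3 (26 and 3 adjusted over the list alone; median -0.50, adjusted p = 0.00275; adjusted p = 0.282 with an estimated correlation). The ATPase subunit PSMC4 was lower (-0.82), while PSMB10 (1.01), a subunit of the immunoproteasome, and PSMA7 (0.66) were higher. In the list of chaperones and associated proteins 31 of 53 were lower and 8 higher (32 and 8 adjusted over the list alone). The median was -0.36 (camera adjusted p = 0.0145, and 0.272 with an estimated correlation). HSPBAP1 lay at -0.96, DNAJC1 at -0.75 and the mitochondrial import factor DNAJC19 at 1.20.

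Translation factors were lower for 25 of 49 and higher for 6 (26 and 6 adjusted over the list alone). Their median was -0.34 (camera adjusted p = 0.0469, and 0.410 with an estimated correlation). EIF3M lay at -1.20, and EIF4EBP1 and EIF4EBP2, repressors of cap-dependent translation, at 1.18 and 1.12. Cell cycle genes were lower for 17 of 29 and higher for 3, the same adjusted over the list alone (median -0.34, adjusted p = 0.0389; adjusted p = 0.628 with an estimated correlation), with CCNB1 at -0.78, CDK1 at -0.79 and E2F1 at 1.44. The mean of the cell cycle list, less that of the 10 arrays, was lowest on DJ-1 arrays 5 and 6 (-0.39 and -0.22). It lay between -0.06 and 0.03 on DJ-1 arrays 1 to 4 and between 0.08 and 0.23 on the IgG arrays. Neither call of translation factors or cell cycle held with an estimated correlation or with the bead set as a block (adjusted p = 0.0672 for both, with medians of -0.31 for both), and both ranged upward from 0.00281 over the alternatives. Within the arrays with fewer and with more beads the adjusted p was 0.0614 and 0.116 for translation factors, and 0.112 and 0.0325 for the cell cycle. Leaving out single arrays also ended these calls, giving an adjusted p of 0.0503, 0.0621, 0.0521 and 0.0542 for translation factors without DJ-1 array 1, 5 or 6 or IgG array 1, and of 0.0621, 0.0683 and 0.0530 for the cell cycle without DJ-1 array 5 or 6 or IgG array 1. For the other lists past the threshold the medians with the bead set as a block were 1.09 for selenoproteins, -0.83 for extracellular matrix, 0.28 for complexes II to V, 0.19 for complex I, 0.21 for cytosolic ribosomal proteins, -0.47 for the proteasome and -0.40 for chaperones, all still past the threshold.

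**Figure D2:**
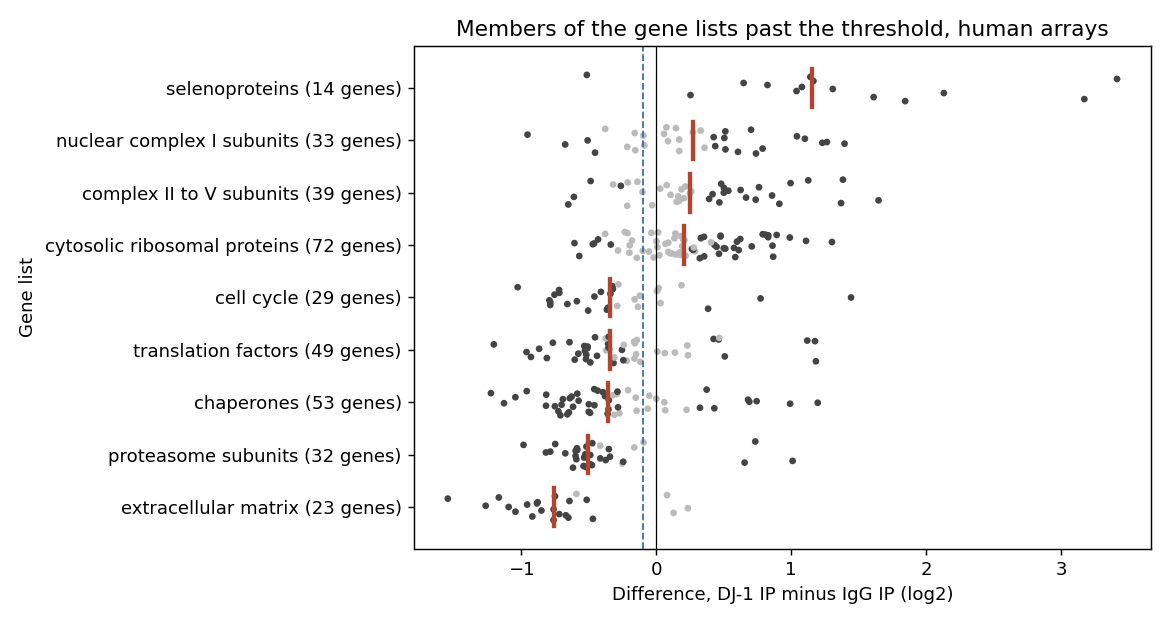
Difference between DJ-1 and IgG immunoprecipitates (log2, horizontal axis) of each measured member of the 9 human gene lists past the threshold; dark points passed the gene-level threshold, grey points did not, red bars are list medians, and the dashed line is the median of all genes at -0.10. Medians run from -0.76 for extracellular matrix to 1.15 for selenoproteins.

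The remaining 14 human lists, of which 1 is not described, did not pass by camera, which compares a list with the other genes. By fry, which does not, 9 of these 14 passed for a net shift of the list. A net shift does not mean that the members moved one way. Glutathione metabolism passed by fry with members called in both directions. Glutathione metabolism had 6 higher and 5 lower of 21 (adjusted p = 0.609), led by GPX4 and by MGST2 at -0.87, and the antioxidant list 4 higher and 11 lower of 23 (0.609), with SRXN1 at 1.38, ferritin light chain FTL at 0.87 and catalase CAT at -0.96. The mean of the antioxidant list was lowest on DJ-1 arrays 5 and 6 (-0.33 and -0.27), against 0.03 to 0.06 on DJ-1 arrays 1 to 4 and 0.09 to 0.12 on the IgG arrays. The MAPK and JNK list had 9 higher and 2 lower of 24 (0.0833), with the JNK scaffold MAPK8IP1 at 1.65, SHC1 at 1.06 and MAPK12 at least 1.89-fold higher, since it was detected on none of the IgG arrays. That list passed without DJ-1 array 3 (adjusted p = 0.0432) and within the arrays with more beads (0.0325), in a range from 0.0325 to 0.257. Parkinsonism genes had 3 higher and 3 lower of 12 (0.736): besides PARK7, PINK1 was at 0.56 and EIF4G1 at 0.46. Adjusted over the list alone, glutathione metabolism had 6 and 4, and the other lists of this paragraph had the same counts.

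Noradrenergic neuroblastoma genes had 1 higher and 9 lower of 14 (median -0.45, adjusted p = 0.0842, past the threshold at 0.0388 with 75th percentile scaling, in a range from 0.0283 to 0.410), with SLC18A1 at -0.86, DDC at -0.64 and GATA3 at -0.53. Neuronal genes had 5 higher and 9 lower of 24 (adjusted p = 0.418), with NRGN at 0.91, VAMP2 at 0.75 (detected on 2 of the 4 IgG arrays) and TUBB3 at -0.71, and astrocyte genes 1 higher and 4 lower of 5 (0.0975), with SOX9 at -0.89, ALDOC at -0.86 and GLUL at -0.53. Mitochondrial ribosomal proteins had 27 higher and 21 lower of 76 (0.418), MRPL33 at 1.55 and MRPL14 at 1.44 against MRPL24. The list of ubiquitin and SUMO enzymes, which also holds SUMO3 itself, had 12 higher and 15 lower of 55 (0.701). UBE2F lay at 1.61, SUMO3 at 1.56 and UBE2S at 1.09. Spliceosome and hnRNP genes had 6 higher and 12 lower of 46 (0.418), with SRSF9 at 1.14, SNRPG at 0.88 and SF3B2 at -0.87. Histones had 2 higher and 7 lower of 27 (0.418), with H2AX at 0.69, H1-2 at -0.90 and H1-5 at -0.79, the latter detected on 1 of the 6 DJ-1 arrays and with overlapping groups. Immediate early genes had 2 higher and 2 lower of 9 (0.736): JUND was higher, while its AP-1 partner JUN (-0.40) and the phosphatase DUSP1 (-0.52) were lower. The list of nuclear receptors and homeobox factors, which also holds SOX genes, had 6 higher and 5 lower of 20 (0.686). NR2F6 lay at 1.32 and SOX8 at 0.98. Adjusted over the list alone, neuronal genes had 5 and 10, mitochondrial ribosomal proteins 28 and 21, and spliceosome genes 5 and 11, and the others were the same. Median and mean differed in sign for glutathione metabolism, ubiquitin enzymes, immediate early genes and nuclear receptors. The sign of the median turned with the scaling for these lists other than immediate early genes, and for histones and the MAPK list. Less the median of all genes it turned for nuclear receptors and histones. JUN and DUSP1 did not pass with 75th percentile scaling.

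The mouse arrays asked which RNAs the same antibody recovered from brain with DJ-1 and not from brain without it. Park7 lay at a log2 intensity of 11.38, 10.80 and 10.80 on the WT arrays and 9.04 on the KO array, and was still detected there. The difference of 1.95 (SE 0.363) was 3.87-fold and did not pass the threshold (adjusted p = 0.692). Whether its probe lies in the deleted part is not known here, so the level is only a partial check of the labels. No gene passed out of 8854 tested by limma (lowest adjusted p = 0.551), and 484 had an unadjusted p under 0.05, of which 281 were higher and 203 lower in WT. The genes with the smallest p that were higher in WT were Snurf, from the imprinted Snrpn locus, Trim3, Eif4a2, Ppfia3 and Gpr162. Snurf, Trim3, Ppfia3 and Gpr162 were detected on all 3 WT arrays and not on the KO array, and lay at least 43.6-fold, 7.92-fold, 8.24-fold and 4.63-fold higher in WT. With the mean of all its probes the log2 difference of Snurf was 2.90. Eif4a2, a translation initiation helicase, was 7.59-fold higher. Lower in WT with the smallest p was the red cell anion exchanger Slc4a1 (-2.28), which was detected on 1 of the 3 WT arrays. Then came the potassium channel Kcnn2 (-1.73), Nacc1 (-1.61), Fbf1 (-1.20) and the lysosomal lipase Lipa (-1.73, detected on 2 of the 3 WT arrays). None of these passed the threshold, with adjusted p from 0.551 to 0.692.

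The WT arrays were not alike. WT array 1 was nearer to the KO array than to the mean of the other WT arrays in 6332 of the 8854 genes (71.5%). Its signals correlated across probes with the KO array at 0.9497 and with WT array 2 at 0.812, whereas WT arrays 2 and 3 correlated at 0.996. Oligodendrocyte genes lay 1.35 above the mean of the 4 arrays on WT array 1 and 1.02 above it on the KO array, and at -1.24 and -1.12 relative to it on WT arrays 2 and 3. The lone KO array has no spread of its own and was assumed to vary like the WT arrays. Without WT array 1, the close pair of WT arrays against the KO array gave 6408 genes past the threshold, 2759 higher and 3649 lower. With the arrays weighted by their spread 6331 passed. In simulated data with the spread of the real arrays, none of 50 genes changed by 3 on the log2 scale was recovered.

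Among 28 mouse lists, red blood cell genes were lower in WT (6 genes, median -2.28, adjusted p = 0.00793 by camera), and spliceosome (40 genes, median 0.23, adjusted p = 0.00961), cell cycle (21 genes, median 0.42, 0.0123) and proteasome lists (33 genes, median 0.07, 0.0452) were higher. With an estimated correlation none passed (adjusted p = 0.938 for each), so these shifts stand only with a preset correlation. No member passed over all genes, and adjusted over the list alone 3 of the red cell genes were lower (Slc4a1, and Hbb-bt and Alas2, named after their values were seen) and 1 translation factor, Eif4a2, was higher. The red cell mean, less that of the 4 arrays, was 1.47 on the KO array and 0.45, -1.08 and -0.85 on the WT arrays, and the spliceosome mean -0.19 against -0.04, 0.11 and 0.12. The cell cycle shift lay in WT arrays 2 and 3 (0.36 and 0.48), since WT array 1 (-0.43) was level with the KO array (-0.41). The proteasome mean was raised mainly by WT array 1 (0.25, with -0.06 and -0.07 on WT arrays 2 and 3 and -0.12 on the KO array). The spliceosome call was lost with 75th percentile scaling (0.0626), and the cell cycle call over probes detected on every array (0.0677). The proteasome call was lost with both 75th percentile scalings (0.429 and 0.142) and with array weights (0.538). It was also lost without WT array 1 (0.586), where its median was -0.02. Without that array 11 lists passed. Oligodendrocyte genes, complex I subunits (median -0.98) and microglia genes (-1.11) were among them, all lower in WT. The complex I mean was 0.90 on WT array 1, above the 0.42 of the KO array. It was -0.65 and -0.67 on WT arrays 2 and 3. Complexes II to V (0.77, KO 0.24) and cytosolic ribosomal proteins (0.73, KO 0.15) were likewise higher on WT array 1. The lower level of complex I subunits in WT thus rests on WT arrays 2 and 3.

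Selenoproteins, which led the human lists, had a median of -0.33 over 20 mouse genes and did not pass (adjusted p = 0.6254), and whether the species differ was not tested. Their mean, less that of all mouse arrays, was 0.24 on the KO array and 0.39, -0.33 and -0.30 on WT arrays 1, 2 and 3. WT array 1 thus lay above the KO array, and the negative median rests on WT arrays 2 and 3. The other mouse lists, of which 1 is not described, did not pass either. Their adjusted p was 0.0726 for oligodendrocyte genes (median -0.81) and chaperones (0.04), 0.133 for translation factors (0.05), 0.187 for microglia (-0.69), choroid plexus (0.10) and histones (0.04), 0.240 for glutathione metabolism (-0.40), 0.257 for complex I (-0.49), 0.456 for extracellular matrix (0.20) and immediate early genes (-0.45), and 0.571 for mitochondrial ribosomal proteins (-0.28) and ubiquitin enzymes (-0.06). It was 0.6254 for the MAPK list (-0.11) and nuclear receptors (0.09), 0.631 for parkinsonism (-0.06), neuron (-0.06) and astrocyte (-0.72) genes, 0.665 for endothelium (-0.16), 0.688 for complexes II to V (-0.33), 0.798 for antioxidant genes (-0.11), 0.846 for noradrenergic genes (-0.12) and 0.856 for cytosolic ribosomal proteins (-0.27). Oligodendrocyte genes passed without WT array 2 (adjusted p = 0.0460) or 3 (0.0350), chaperones without WT array 3 (0.0409) and histones without WT array 2 (0.0389). The scaling moved the median of all mouse genes from -0.28 to 0.09. The sign of the median turned with the scaling for the proteasome, chaperone, choroid plexus, endothelium, extracellular matrix, histone, translation factor, MAPK, noradrenergic, parkinsonism and ubiquitin lists. These turns in large part follow the shift of all genes. Less the median of all genes the sign turned for the endothelium, noradrenergic, ubiquitin, antioxidant and neuron lists, and the others kept theirs. Median and mean differed in sign for the MAPK, noradrenergic, parkinsonism and ubiquitin lists. Camera placed the antioxidant and neuron lists above other genes although their medians and means were negative.

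**Figure D3:**
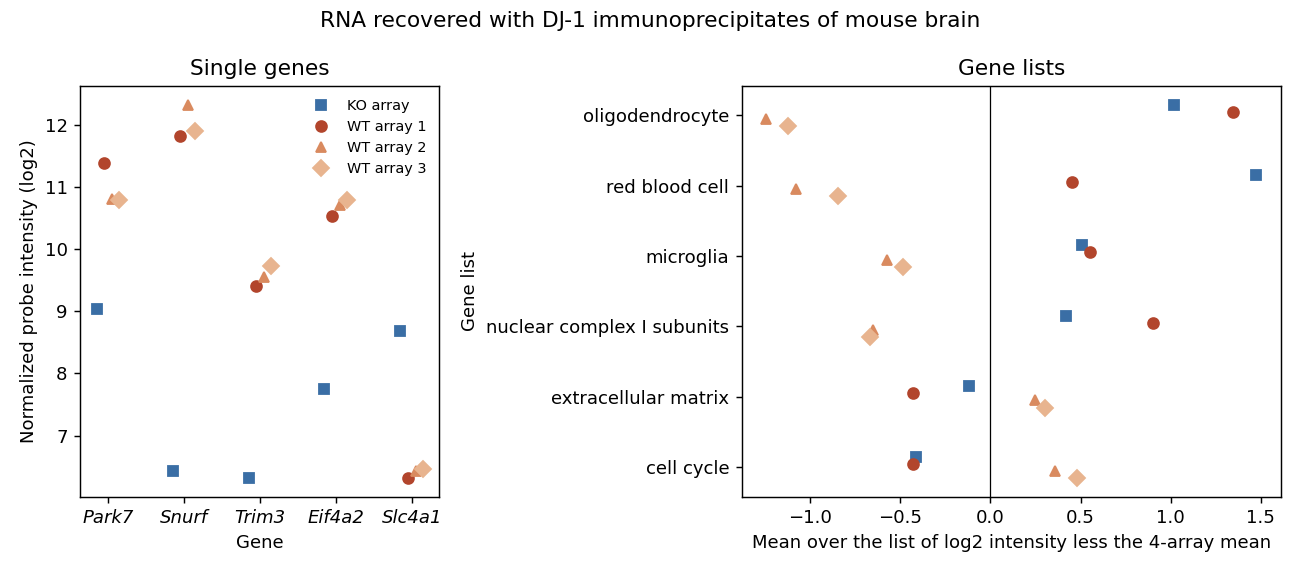
Left, normalized probe intensity (log2) of 5 genes on the KO array and each of the 3 WT arrays; right, mean over each gene list of the log2 intensity less the mean of the 4 arrays. Park7 lies at 9.04 on the KO array and between 10.80 and 11.38 on the WT arrays, while for oligodendrocyte genes WT array 1 (1.35) lies beside the KO array (1.02).

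The differences in the 2 species were compared over 5344 genes with the same symbol. Across genes, which are not independent replicates, the human difference (DJ-1 less IgG) and the mouse difference (WT less KO) had a Spearman rho of -0.22 and a Pearson r of -0.19. Of the 1449 human genes higher with DJ-1, 92 were among the 500 mouse genes with the highest difference, where 136 would be expected by chance (odds ratio 0.579, one-sided Fisher exact p = 0.999999). Taken singly against the KO array, WT arrays 1, 2 and 3 gave a rho of 0.07, -0.25 and -0.25, and 180, 85 and 87 shared genes, so the sign for WT array 1 is opposite to that of the other 2.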

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

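The rule for a far array compared the gap between an array and its nearest neighbour with the range of its group, over 172 groups of values from the human arrays, and marked 9. Chance alone marks about 1 in 20 groups, so as many are expected. The rule looks for single arrays and cannot mark 2 far arrays that lie together. DJ-1 arrays 5 and 6 lay together and apart from arrays 1 to 4 for PTN (5.18 and 5.31, others 7.87 to 8.08). They did so for IGF2 as well (13.64 and 13.15, others 11.38 to 11.75), and neither gene was marked. DJ-1 array 6 stood apart for C1GALT1C1 (log2 intensity 7.30, other arrays 6.61 to 6.82), UQCRQ (11.56, others 11.71 to 11.76), RPS12 (11.46, others 11.80 to 11.98), PSMB10 (9.44, others 9.89 to 10.15) and CCNB1 (11.15, others 10.89 to 10.99). DJ-1 array 5 stood apart for CTSV (6.64, others 7.24 to 7.34) and DJ-1 array 4 for EIF4G1 (11.89, others 11.39 to 11.51). IgG array 4 stood apart for TRIOBP (6.55, others 6.18 to 6.22) and NDUFB10 (8.93, others 8.58 to 8.63). In each case the array stayed on the side of its own group, and 5 of the 9 were on DJ-1 array 6.

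Probes without a single gene symbol were outside the comparisons of genes. Of 1882 tested, 431 were higher with DJ-1 than with IgG and 338 lower.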

How the results depend on the processing

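The alternatives for bead sets, header numbers, averaged arrays, the 75th percentile over detected probes and single WT arrays were chosen after seeing the data. The human gene count stayed between 3389 and 6098 under the alternatives over all arrays, and 4339 to 5108 with 1 array left out; within the arrays with more beads it was 839, where 3 arrays stood against 1. The named human genes kept their direction in every setting run. All but PARK7 were picked for groups that do not overlap or for a small p on these same arrays. Much of that agreement is therefore built in. Within the arrays with more beads 30 of the 85 lost their call, PARK7 among them (0.42, adjusted p = 0.253; 0.43 over all arrays). JUN lost it with the close arrays averaged (adjusted p = 0.0502), JUN and DUSP1 with 75th percentile scaling and PTN at a threshold of 0.01. The count of 9 human lists became 2 with an estimated correlation and 5 at a threshold of 0.01, with 6 to 10 when 1 array was left out. With the header number as a replicate block 5860 genes and 7 lists passed, and translation factors and cell cycle lost their call (adjusted p = 0.0774 and 0.136). The human detected share differed by 0.982 points at a score above 0.95 (exact permutation p = 0.00952), and by 0.535 to 1.17 with 1 array left out. The mouse gene count of 0 became 6331 with array weights and ranged from 0 to 6408 with 1 WT array left out. The count of 6408 came without WT array 1, where 2 near-identical arrays set the spread. Averaging those 2 arrays with WT array 1 kept gave 0. Averaging them without WT array 1 was not run, so the 0 does not show what gave the 6408. The 4 mouse lists became 2 with 75th percentile scaling, 11 with array weights, 0 with an estimated correlation and 2 at a threshold of 0.01, and ranged from 6 to 11 with 1 array left out. The species comparison stayed between -0.27 and -0.15 except for WT array 1 alone (rho 0.0739, odds ratio 1.58), and -0.25 to -0.18 with 1 array left out. The cause of these changes between settings was not tested. In 1 fit the array weights stopped short of their tolerance. A slide block was not run, as the files name no slides. Of the called human genes 99.6% had the same direction in the deposited values. Those values are means of the same arrays, so this agreement is largely built in. Probes near background limit folds of dim genes.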

Other observations

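The tests below on array sets, mouse arrays, scaling and cell makeup were chosen after the result was seen; the counts of splits and the test of 3 lists of membrane and secretory genes were set before their results were seen, although those lists were drawn up after the data were examined and the gene count of the split between bead sets was already known. Genes lower with DJ-1 included 3 further groups of proteins made at the endoplasmic reticulum. Without the 40 most lowered genes, 15 of 26 lysosomal genes were lower and 1 higher (median -0.52), 21 of 28 genes of folding and translocation in the endoplasmic reticulum were lower and 3 higher (median -0.59), and 11 of 16 integrins, cadherins and other adhesion receptors were lower and 0 higher (median -0.60). By camera the adjusted p was 0.00183, 0.000772 and 0.00183, and 0.0730 for each with an estimated correlation.

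Extracellular matrix genes were lower with DJ-1 than with IgG by camera with the preset correlation, a call lost with an estimated one (adjusted p = 0.0653). The list's median less that of all genes was at most -0.49 under the scalings tried. A factor per array moves all genes alike and cannot change this measure. Both 75th percentile scalings thus gave the same value (-0.72) and do not test such a factor. Quantile normalization with and without background correction (-0.66 and -0.49) and z scores (-0.70) can change it. For these, scaling is argued against as the cause. A lower recovery of many messages translated at the endoplasmic reticulum is a candidate explanation, as the 3 lists above lay lower (highest adjusted p 0.00183 with the preset correlation, 0.0730 with an estimated one), but not of all: IGF2 (6.00), SCARA3 (2.86), GPX3 (1.85) and, named after their values were seen, SELENOK, SELENOM, SELENON, SELENOS and SELENOT (0.65 to 1.31) were higher. More matrix-producing cells in the cultures of the IgG arrays stay open: noradrenergic genes whose proteins are neither secreted nor in membranes lay at -0.0418 relative to all genes (SE 0.123, 8 genes), which does not decide it. The test was narrowed to these after the whole list was seen to lie at -0.30 (SE 0.117, 14 genes), which speaks against such cells unless secreted and membrane members are lower for another reason, and no unprecipitated RNA was analysed here.

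The human count of 4911 genes was set against other groupings of the arrays: of 100 splits of the 10 arrays out of 210, taken at random apart from the real split and that between the bead sets, 1 gave as many, the real one, and the highest of the others, 183, was the split between the bead sets, so chance can be excluded for the gene count as far as the arrays are independent. Should arrays of a group share a culture, the splits cover array noise and not differences between cultures. The bead sets are argued against as the cause of the gene count. With the set as a block 5281 genes passed. Over all genes tested the differences within the 2 sets correlated at a Pearson r of 0.850. Of the called genes 99.6% had their direction within both sets, but they were called on these same arrays. Part of that agreement is therefore built in. For the count of 9 shifted lists chance cannot be excluded: 8 of the 100 splits gave as many, the highest of the others 11. Of the 7 others, 6 kept much of the real contrast, with 2 or 5 of the DJ-1 arrays in the group of 6. The remaining 1 was among the 86 splits with 3 or 4. For both counts the splits were drawn without regard to the bead sets, so some also carry the difference between those sets. Splits within the sets were not run.

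Mouse WT array 1 lay nearer the KO array than WT arrays 2 and 3. Exchanged labels are argued against by Park7, whose level on the KO array less that of the lowest WT array was -1.76 on the log2 scale. A shared production set of arrays is argued against by the bead numbers. Their correlation between WT array 1 and the KO array less the highest across the sets was -0.0461. The KO array correlated at 0.237 and 0.255 with WT arrays 2 and 3. WT array 1 correlated at 0.204 and 0.199 with them and at 0.209 with the KO array. The contrast thus rests on the KO array, and bead numbers do not cover hybridization. Brain with less myelin and more immature neural cells on WT arrays 2 and 3 may be the source: oligodendrocyte genes lay lower there (mean difference -2.53, SE 0.405, 18 genes) and genes of immature neurons and progenitors, without those seen beforehand or the 40 most raised, 1.15 higher (SE 0.215), with 14 of 17 higher on both arrays. The labels give no age or region for single arrays, and a difference in RNA quality or labelling was not tested.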
